A study of Mus musculus with 8 samples.

How the data were processed

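Total RNA from the duodenum of 4 infected and 4 uninfected mice was turned into biotin-labelled cRNA and hybridised to 1 single-colour array per mouse, per the labels' protocols; the probe set names are those of an Affymetrix array. The deposited table holds 1 value per probe set and mouse, an intensity on a linear scale without negative values, as the authors deposited it. The mean of each column after trimming 2% of values at either end lay between 500.4 and 500.5, so the deposited columns appear to have been scaled to a common level, a step that no label states. The software that summarised the probes into probe sets, and its version, are not given in the sources used here. Scaling to a common mean makes every change relative to the average transcript, and a probe set summary has no stated background level, so that the signals of the yeast control probe sets (up to 58.1) served as a reference for low values. The number of arrays, and not a read depth, limits the precision.

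From these values, log2(value + 16) was computed. A rule written beforehand called for quantile normalisation (limma) if a quartile differed by more than 0.1 between arrays; the largest such range was 0.115, and quantile normalisation was applied. The fold changes are on the log2(value + 16) scale, which understates the change of genes with low signal. Of 12488 probe sets, 66 controls were left out. Of the other 12422, 10833 carried 1 gene symbol in the platform annotation, 396 several and 1193 none; 10817 were matched by Entrez identifier to the RefSeq gene table of assembly GRCm38.p6, which changed the symbol of 0. Where a gene had several probe sets (2073 genes), the brightest over all arrays stood for it, which left 8251 genes; that probe set was kept in every alternative that did not concern the probe set. No coordinates are given, because no genome build is named with the table.

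Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend, 6 residual degrees of freedom), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Altogether 39 gene lists fixed before the data were examined, for the tissue's cell types, for immune responses and for digestive and metabolic functions, were tested with camera (limma) at a preset correlation of 0.01, adjusted over the lists, and beside it with an estimated correlation and with fry; of 865 list entries 618 were measured, and 12 genes stood in more than 1 list. The infected and the uninfected mice carried the same numbers 1 to 4 in the labels; the correlations of the deviations of equally numbered mice are given with the alternatives. The labels describe the samples as 4 infected and 4 uninfected mice, so that replicates are animals.

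The genes named were chosen by a rule written before the data were examined: the 12 largest increases and 12 largest decreases among called genes whose groups did not overlap, up to 4 members with the smallest p of each list described, and a fixed set of genes of mucosal immunity and digestion, of which 2 were not analysed here. Genes named outside this rule, which were Vil1, Reg3b, Reg3g, Cma1, Kit, Tpsab1, Igkv4-70, Ugt2b34, Adh1, Znrf2, Slc6a20b and those of the closing section that are not in a list, were chosen after their values were seen.

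The fit was tested on simulated data with the means and spreads of the 8251 genes and 200 changed genes, 4 against 4. It recovered 47.8% of genes changed 1.5-fold, 61.2% of those changed 2-fold and 89.4% of those changed 4-fold, with 6 false calls, and it made 0 calls where no gene was changed. The list test called the 1 shifted list and 0 others. Genes were simulated independently, whereas those of a list can vary together (mean correlation within groups up to 0.582, in the exocrine pancreas list). The simulation therefore does not measure false list calls where genes vary together. Alternatives covered the normalisation, the value added before the log, a filter on the dimmest genes (the lowest 33.3% by mean signal), the choice of probe set, the variance model, array weights, the mouse number as a block, the threshold, the list test and leaving out each mouse. Leaving out pairs of uninfected mice was added after the data were seen. RNA quality was checked by the ratio of 3' to 5' probe sets: for actin it was 1.47 ± 0.205 in infected and 1.31 ± 0.121 in uninfected mice (SD, n = 4; exact permutation test, two-sided p = 0.2). Figures were drawn with matplotlib 3.10.9.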

Results

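Gene expression was measured in the duodenum of 8 female C57BL/6 mice aged 7 weeks. Of these, 4 mice had received 1000000 trophozoites (the feeding stage) of the intestinal parasite Giardia duodenalis, strain GS, by stomach tube. They were killed after 10 days, and 4 mice were uninfected. The RNA of each mouse was hybridised to 1 array with 12488 probe sets, and the median signal of an array lay between 125.2 and 136.6. Across probe sets, 2 arrays of the same group correlated with a mean Pearson r of 0.969 ± 0.0018 (SD, 12 pairs), and 2 arrays of different groups with 0.965 ± 0.0023 (SD, 16 pairs). Probe sets are not independent replicates, so no p-value belongs to these values. The first principal component held 22% of the variance and placed the infected mice between 11.13 and 23.92 and the uninfected mice between -27.13 and -5.35. Gene signals are given as mean ± SD over 4 mice per group, and log2 changes (infected minus uninfected) with ± SE from limma.

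The comparison asks which transcripts of the duodenum differed between infected and uninfected mice. Transcripts of the mast cell proteases Mcpt1 and Mcpt2 were raised most among the called genes. Of 13 genes of plasma cells 4 rose, and of 32 genes that metabolise foreign compounds 8 fell. Both of these lists were called by camera with its preset correlation, but not with an estimated correlation (adjusted p = 0.0965 and 0.0651 with an estimated correlation). Of 8251 genes tested, 30 were higher and 30 were lower in infected mice (limma, Benjamini-Hochberg adjusted p under 0.05). The change was at least 2-fold in 20 of the higher genes and in 5 of the lower genes, and the smallest called change was 1.36-fold. In all 60 genes the 4 infected mice lay on one side of the 4 uninfected mice. Over all genes tested this held for 503 (6.1%), where chance alone gives 2.86%. With 1 mouse left out at a time, 31 of the 60 genes kept their call in each of the 8 fits. The count of all called genes was 35 without uninfected 2 and 38 without infected 4. The count of lower genes was 13, 14, 18, 19 and 15 without uninfected 1, uninfected 2, uninfected 3, infected 3 and infected 4. Without an intensity trend in the variance, limma called 23 higher and 4 lower genes, and 20 of the 60 genes kept their call. Among the genes named here, Abcb1a, Adh1, Arfgap2, Casp1, Ccl9, Ces1d, Clca1, Cyba, Dipk2a, Gpx2, Gsta4, Gstk1, Gstm2, Hsd17b4, Idh1, Igh-VS107, Ighg3, Igkv4-70, Il18, Itln1, Jchain, Mfsd4a, Mmp7, Nhlh1, Pdgfra, Retsat, Slc46a1, Slc6a20b, Ugt2b34, Ugt2b5 and Znrf2 lost it in that fit. Their adjusted p ran from 0.0526 for Ces1d and Nhlh1 to 0.235 for Hsd17b4. Of 39 gene lists, 14 were called by camera with a preset correlation (5 higher, 9 lower), 1 with an estimated correlation and 7 by fry. The unadjusted camera p also rose where the correlation was estimated below the preset 0.01. It went from 0.00297 to 0.0189 for nitric oxide and arginine metabolism (estimate -0.029) and from 0.0079 to 0.0346 for fat absorption (0.006). A call lost with an estimated correlation thus need not mean that the genes of a list varied together. Fry did not call the goblet cell, B cell, MHC class I, proliferation, fatty acid oxidation, enteroendocrine, exocrine pancreas and distal intestine lists that camera called (adjusted p = 0.0516, 0.312, 0.0516, 0.105, 0.154, 0.132, 0.434 and 0.136).

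The proteases Mcpt1 and Mcpt2, stored in the granules of mucosal mast cells, had the largest log2 increases of all genes that passed. The signal of Mcpt2 was 13500 ± 5512 in infected and 113 ± 49.6 in uninfected mice, a log2 change of 6.65 ± 0.33 (limma adjusted p = 8.73e-07). That of Mcpt1 was 12370 ± 4408 against 148 ± 33.8, a log2 change of 6.18 ± 0.25 (limma adjusted p = 2.16e-07). The chymase gene Cma2 rose from 90.2 ± 20.3 to 2260 ± 570.3 (log2 change 4.41 ± 0.19) and the carboxypeptidase gene Cpa3 from 19.7 ± 10.2 to 550.3 ± 190.4 (3.97 ± 0.30). Whether the probe set of Cma2 also takes up signal of Mcpt1 or Mcpt2 was not tested. Fcer1a, the alpha chain of the high-affinity IgE receptor, rose from 11.6 ± 10.6 to 133 ± 51.4 (2.43 ± 0.34). Of 13 measured mast cell genes, 5 rose and 8 did not pass the test; 7 were higher when adjusted over the list alone. Among those that did not pass, the log2 change was 0.82 ± 0.34 for Mcpt4, a protease of connective tissue mast cells, 0.08 ± 0.26 for Cma1, 0.34 ± 0.20 for Kit and -0.14 ± 0.20 for Tpsab1. The mean signal of Mcpt4 stayed below that of the brightest yeast control (58.1) in both groups. The list rose as a whole (camera, Benjamini-Hochberg adjusted p = 6.76e-18). It was the only 1 of 39 lists still called with an estimated correlation (adjusted p = 0.0387 with an estimated correlation). The uninfected means of Cpa3 and Fcer1a also lay below the yeast control. Their log2 changes depended on the value added before taking logs (4.84 and 3.69 with 1 added, 2.83 and 1.35 with 64 added, in place of 16), as did that of Mcpt4 (1.45 and 0.35). Without uninfected 1 and 2 together the change of Fcer1a was 2.22 and its call was lost (adjusted p = 0.115).

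**Figure D1:**
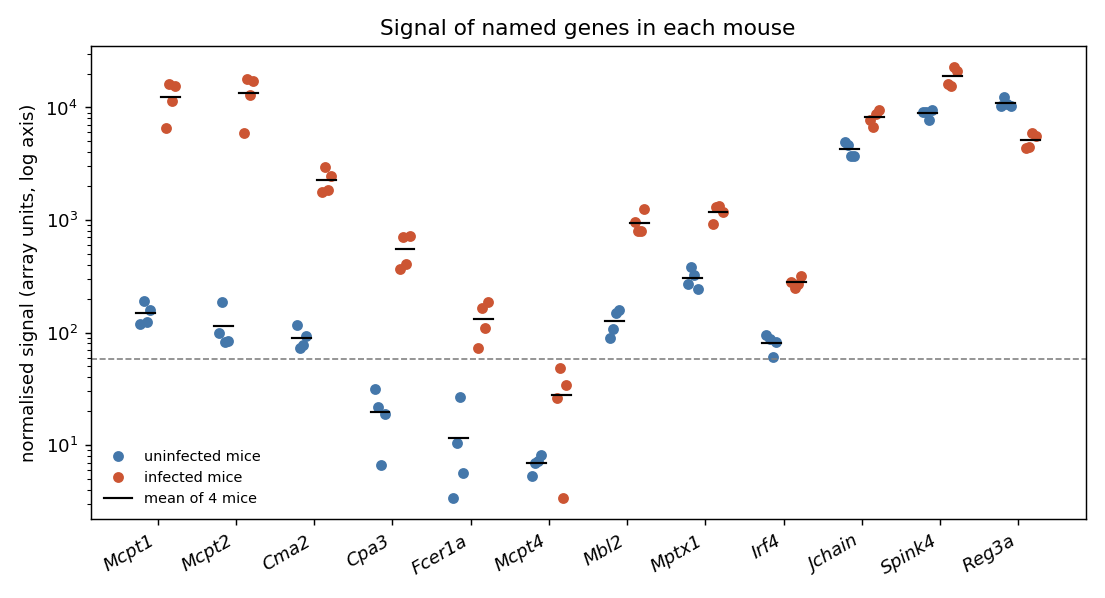
Normalised array signal (log axis) of 12 genes in each of 4 uninfected mice (blue) and 4 infected mice (orange); short black lines are group means and the dashed line is the highest signal of the yeast control probe sets, 58.1. The infected mice lie above all uninfected mice for every gene shown except Mcpt4, where the groups overlap, and Reg3a, where they lie below.

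Of 13 measured genes of antibody-secreting plasma cells, 4 rose. Irf4, a transcription factor of plasma cell differentiation, rose from 81.4 ± 15 to 278.7 ± 28.1 (log2 change 1.61 ± 0.18; limma adjusted p = 0.00158), and Jchain, the peptide that joins IgA and IgM monomers, from 4267 ± 657.4 to 8226 ± 1219 (0.94 ± 0.13). The coactivator Pou2af1 (1.38 ± 0.22) and the immunoglobulin heavy chain gene Ighg3 (1.09 ± 0.20) also rose. So did the immunoglobulin variable genes Igkv10-96 (1.61 ± 0.17), Igkv4-70 (1.16 ± 0.18) and Igh-VS107 (1.65 ± 0.30), which were in no fixed list. A probe set annotated to Igkv4-70 together with other immunoglobulin genes rose by 1.14 ± 0.19. Related immunoglobulin genes may thus share signal, and these increases need not be separate. The heavy chain of IgA, Igha, had a signal of 60930 ± 3640 in infected and 42840 ± 5750 in uninfected mice and did not pass the test (0.52 ± 0.12; limma adjusted p = 0.0868), though the groups did not overlap. It passed in the as-deposited values (adjusted p = 0.0295), without the dimmest genes (0.0236), as the mean of its probe sets (0.00971) and with robust variances (0.0209). Pigr, the receptor that carries IgA across the epithelium, changed by 0.10 ± 0.10 and did not pass. The other 9 genes of the plasma cell list did not pass, and 7 of the 13 were higher when adjusted over the list alone. The list rose by camera (adjusted p = 1.05e-08; adjusted p = 0.0965 with an estimated correlation). With 1 mouse left out, Ighg3 lost its call in 6 of 8 fits (adjusted p up to 0.117 without uninfected 2), Igh-VS107 in 6 (up to 0.127 without infected 4) and Pou2af1 in 3 (up to 0.0716 without infected 4).

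None of 15 B cell genes passed the test alone, nor when adjusted over the list alone, while all 15 had a positive log2 change. Cd79b, part of the B cell receptor, was at 418 ± 236 in infected and 170 ± 101 in uninfected mice (1.21 ± 0.44), and Vpreb3 changed by 0.69 ± 0.24 (0.44 with 64 added before taking logs). The B cell list rose by camera (adjusted p = 0.00112; adjusted p = 0.407 with an estimated correlation). Its mean log2 signal was 6.64, 6.40, 7.62 and 7.23 in infected 1 to 4 and 6.25, 6.53, 6.18 and 6.93 in uninfected 1 to 4, so that the groups overlapped. Of 30 cell proliferation genes, 27 had a positive change and none passed alone or adjusted over the list alone. The changes were 0.39 ± 0.12 for Cdk1, the kinase that drives entry into mitosis, and 0.35 ± 0.15 for Top2a (0.58 without uninfected 1 and 2). That list rose by camera (adjusted p = 2.24e-05; adjusted p = 0.244 with an estimated correlation).

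**Figure D2:**
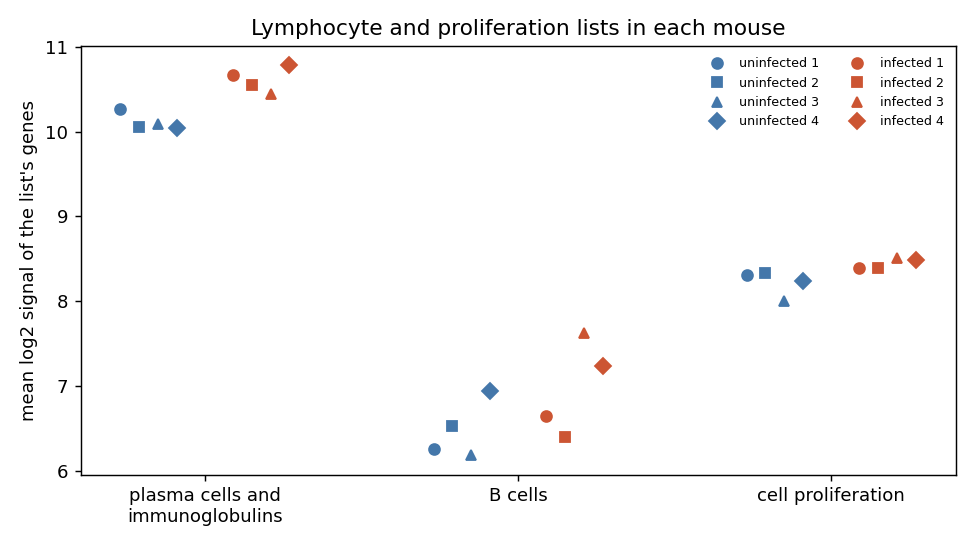
Mean log2 signal of the genes of 3 fixed lists in each mouse; colour gives the group and the marker shape the mouse number. The plasma cell list lies between 10.44 and 10.78 in infected mice and between 10.04 and 10.26 in uninfected mice, while the B cell list overlaps between the groups.

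Among secretory cells of the epithelium, Spink4, a peptide of goblet cells, rose from 8857 ± 759.1 to 18890 ± 3598 (1.08 ± 0.13; limma adjusted p = 0.00242), and Clca1, a secreted component of mucus, from 18280 ± 3118 to 29370 ± 3647 (0.69 ± 0.13; adjusted p = 0.038). Retnlb, a resistin-like protein of goblet cells, was at 94.6 ± 66.5 against 15.7 ± 15.7, the latter below the yeast control, and did not pass (1.69 ± 0.47; adjusted p = 0.188). Its change was 2.65 with 1 and 0.91 with 64 added before taking logs. The mucin Muc3 did not pass either (-0.68 ± 0.14; adjusted p = 0.06). It passed without infected 3 (adjusted p = 0.0173), without the dimmest genes and with robust variances (0.0285 in both). Of 14 goblet cell genes 2 rose and 12 did not pass; 4 were higher and 1 was lower when adjusted over the list alone. The goblet list rose by camera (adjusted p = 0.013; adjusted p = 0.236 with an estimated correlation). The call of Clca1 was lost in 6 of 8 fits without 1 mouse (adjusted p up to 0.13 without uninfected 3), and that of the goblet list by camera on ranks (0.11) and without uninfected 1 and 2 (0.135).

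Of 8 genes of Paneth cells and antimicrobial proteins, 2 rose, 1 fell and 5 did not pass. Adjusted over the list alone, 3 were higher and 1 was lower. A further 13 genes of this list, among them Lyz1, Ang4 and most of its defensins, were not analysed. Mmp7, the protease that activates Paneth cell defensins, rose from 1610 ± 290.6 to 3284 ± 687.8 (1.01 ± 0.16), and the lectin Itln1 from 19640 ± 3108 to 30910 ± 4197 (0.66 ± 0.13). Reg3a, a secreted antimicrobial lectin, fell from 11020 ± 1009 to 5101 ± 805.4 (-1.12 ± 0.11; limma adjusted p = 0.000775). The log2 change was 0.05 ± 0.20 for Reg3b and -0.03 ± 0.18 for Reg3g, neither of which passed. The Paneth list was not called by camera (adjusted p = 0.0656). It was called without uninfected 2 (0.0216), uninfected 3 (0.015) or infected 1 (0.0472). The call of Itln1 was lost in 6 of 8 fits without 1 mouse (adjusted p up to 0.157 without uninfected 1). Cd24a, a surface protein in the tuft cell list that other cells also carry, rose from 2906 ± 422 to 5875 ± 607.3 (1.02 ± 0.11). The other 5 of 6 tuft cell genes did not pass, 2 were higher when adjusted over the list alone, and the list was not called (adjusted p = 0.0591). It was called without uninfected 3 (0.015), infected 1 (0.0363) or infected 3 (0.0456), without the dimmest genes (0.0178), as means of probe sets (0.0353) and with array weights (0.0479). None of 13 stem cell and crypt base genes passed, 2 were higher when adjusted over the list alone, and the list was not called (adjusted p = 0.0591). This list was called without uninfected 2 (0.0442) or infected 3 (0.0409), as means of probe sets (0.0489) and by fry (0.0126). Among its genes the changes were 0.99 ± 0.23 for Ephb3, which passed without an intensity trend (adjusted p = 0.0406), and 1.19 ± 0.35 for Cd44. With 64 added before taking logs they were 0.56 and 0.61, and that of Cd44 was 1.88 with 1 added and 0.58 as the mean of its probe sets.

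Of 32 measured genes of xenobiotic metabolism, 8 fell. Gsta4, a glutathione transferase, fell from 1575 ± 256 to 514.3 ± 214 (log2 change -1.66 ± 0.25; limma adjusted p = 0.00942), and Ugt2b5, a glucuronosyltransferase, from 3195 ± 694.5 to 1067 ± 334.9 (-1.60 ± 0.22; adjusted p = 0.00609). Aldh1a1, an aldehyde dehydrogenase that also makes retinoic acid, fell from 23740 ± 1709 to 12260 ± 2011 (-0.96 ± 0.12; adjusted p = 0.00252), and the peroxisomal and mitochondrial glutathione transferase Gstk1 from 3161 ± 102.7 to 2178 ± 87.6 (-0.53 ± 0.07; adjusted p = 0.003). The efflux pump Abcb1a (-0.85 ± 0.16), the carboxylesterase Ces1d (-0.81 ± 0.13), the glucuronosyltransferase Ugt2b34 (-0.54 ± 0.10) and the alcohol dehydrogenase Adh1 (-0.45 ± 0.08) fell as well. None of the 32 rose and 24 did not pass, and 22 were lower when adjusted over the list alone. A negative change was seen in 29, and the median log2 change was -0.52. The list fell by camera (adjusted p = 4.46e-19; adjusted p = 0.0651 with an estimated correlation). Without uninfected 1 and 2 its median log2 change was -0.46, and each of the 8 genes lost its call (adjusted p from 0.0773 for Aldh1a1 to 0.304 for Abcb1a). Gstm2, a further glutathione transferase outside the list, fell by 0.86 on the log2 scale. With 1 mouse left out, the calls of Abcb1a, Ugt2b34 and Gstm2 were each lost in 6 of 8 fits and those of Ces1d and Adh1 in 5. Their adjusted p reached 0.117 without uninfected 2, 0.127 without infected 4, 0.124 without infected 4, 0.0637 without uninfected 3 and 0.0631 without uninfected 2. A second probe set of Ces1d, nearly as bright (mean log2 signal 8.45 against 8.47), changed by -0.41 ± 0.21.

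**Figure D3:**
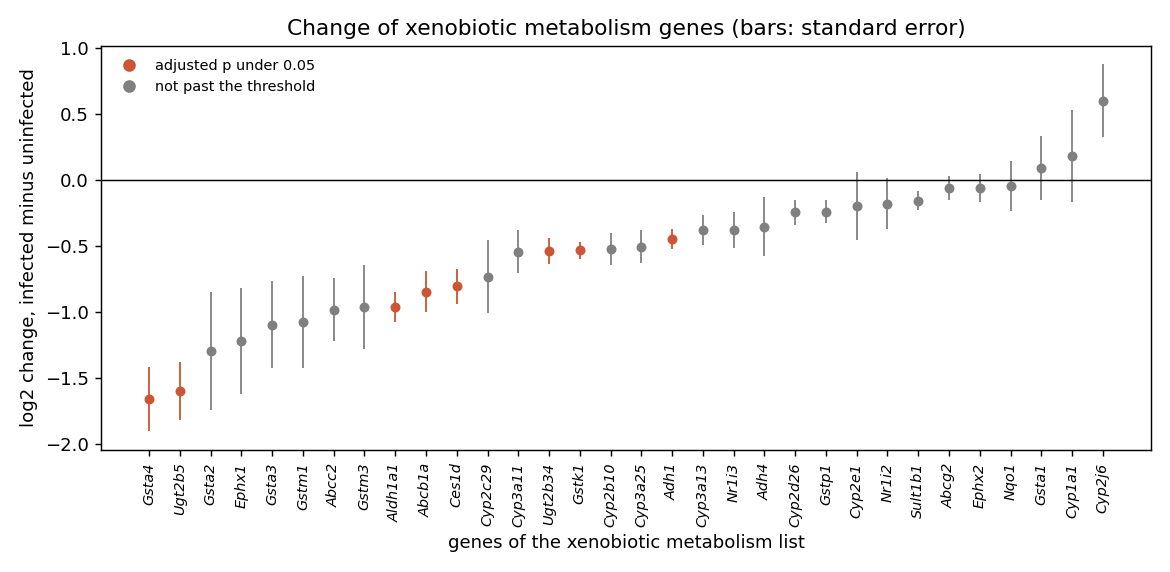
Log2 change (infected minus uninfected) of the 32 measured genes of xenobiotic metabolism, in order of change, with bars of 1 standard error from the fit to 4 and 4 mice; orange points passed the adjusted p of 0.05 over all genes. The 8 orange points run from -1.66 for Gsta4 to -0.45 for Adh1, and 29 of the 32 points lie below 0.

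No single gene passed in the lists of brush border enzymes, fat absorption, fatty acid oxidation and enteroendocrine cells. Of the 16 genes of the nutrient transporter list, the folate transporter Slc46a1 fell (5822 ± 595.1 to 3601 ± 684.9; -0.70 ± 0.13; limma adjusted p = 0.0334). Its call was lost in 5 of 8 fits without 1 mouse (adjusted p up to 0.121 without infected 4). The other 15 did not pass, 1 of the 16 was lower when adjusted over the list alone, and the list was not called (adjusted p = 0.294). Outside the list the amino acid transporter gene Slc6a20b fell from 1403 ± 197.7 to 809.3 ± 160.8 (-0.79 ± 0.15; limma adjusted p = 0.0377). Its call was lost in 6 of 8 fits without 1 mouse (adjusted p up to 0.125 without uninfected 1). The glucose transporter Slc5a1 changed by 0.17 ± 0.16. None of 13 brush border genes passed and 3 were lower when adjusted over the list alone. The change was -2.32 ± 0.60 for the alkaline phosphatase Akp3, which passed without infected 2 (adjusted p = 0.00912). It was -0.28 ± 0.09 for Mme, -0.13 ± 0.08 for lactase, Lct, and 0.02 ± 0.07 for villin, Vil1. The brush border list fell by camera (adjusted p = 0.0027; adjusted p = 0.148 with an estimated correlation). None of 16 fat absorption genes passed or was called when adjusted over the list alone. The change of Apoa4, an apolipoprotein of chylomicrons, was -0.20 ± 0.10. That list fell by camera (adjusted p = 0.0237; adjusted p = 0.225 with an estimated correlation), but not without uninfected 4 (0.0953) or infected 4 (0.0655). None of 22 genes of fatty acid oxidation passed and 2 were lower when adjusted over the list alone. The changes were -0.54 ± 0.15 for Acadl and -0.35 ± 0.10 for Acaa1b. The list fell by camera (adjusted p = 0.00113; adjusted p = 0.256 with an estimated correlation). None of 20 enteroendocrine genes passed and 3 were lower when adjusted over the list alone, among them the hormones Sct (-0.28 ± 0.08) and Cck (-0.45 ± 0.12). The enteroendocrine list fell by camera (adjusted p = 0.0181; adjusted p = 0.244 with an estimated correlation), but not without uninfected 2 (0.0545), uninfected 3 (0.0775), infected 1 (0.062) or uninfected 1 and 2 together (0.0701).

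**Figure D4:**
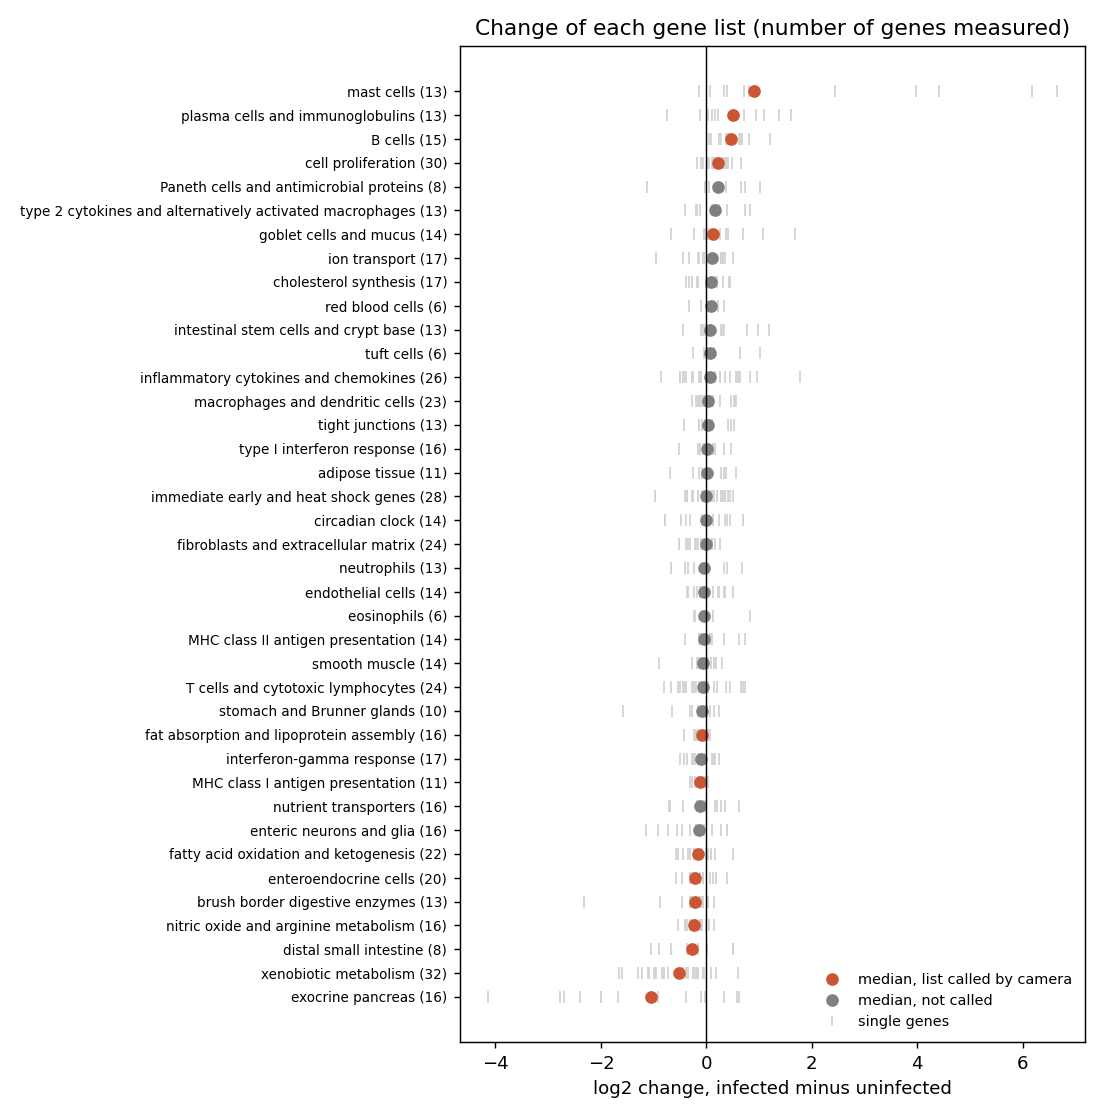
Log2 change (infected minus uninfected) of the genes of 39 lists fixed beforehand; grey ticks are single genes, circles are list medians, and orange circles mark the 14 lists called by camera with the preset correlation. The mast cell list has the highest median, 0.90, and the exocrine pancreas list the lowest, -1.05.

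Inflammatory genes moved singly. The cytokine Il18 fell from 2016 ± 266.9 to 1108 ± 183.9 (-0.86 ± 0.13; limma adjusted p = 0.0115). The chemokine Ccl9 rose from 571 ± 49.1 to 1041 ± 217.6 (0.83 ± 0.14; adjusted p = 0.0206), and its call was lost in 5 of 8 fits without 1 mouse (adjusted p up to 0.0767 without uninfected 2). The other 24 of 26 inflammatory cytokines and chemokines did not pass; 2 were higher and 3 lower when adjusted over the list alone, and the list was not called (camera adjusted p = 0.817). The mean signals of Il4, Il13, Il6, Tnf, Ifng, Il17a, Nos2 and Arg1 were all below the yeast control in both groups, and none of them passed. None of 16 genes of nitric oxide and arginine metabolism passed and 2 were lower when adjusted over the list alone. Values were -0.30 ± 0.07 for ornithine transcarbamylase, Otc, and -0.31 ± 0.09 for arginase Arg2 (-0.08 as the mean of its probe sets). This list fell by camera (adjusted p = 0.0116; adjusted p = 0.148 with an estimated correlation), but not without the dimmest genes (0.0636). None of 11 MHC class I genes passed and 2 were lower when adjusted over the list alone, with -0.27 ± 0.07 for H2-Q1 and -0.30 ± 0.08 for the immunoproteasome subunit Psmb8. The MHC class I list fell by camera (adjusted p = 0.00279; adjusted p = 0.236 with an estimated correlation).

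No gene passed in the lists of T cells (camera adjusted p = 0.294) or of macrophages and dendritic cells (0.508). Adjusted over the list alone, 1 of 24 T cell genes was lower and 1 of 23 macrophage genes higher. None passed, nor was called when adjusted over the list alone, in the lists of eosinophils (0.835), neutrophils (0.773), type 2 cytokines (0.294), the interferon-gamma response (0.359), the type I interferon response (0.926) and MHC class II (0.817). In both groups the means of 5 of 6 eosinophil, 8 of 13 neutrophil and 8 of 13 type 2 genes did not exceed the brightest yeast control. A further 5, 2 and 8 genes of these 3 lists were not analysed. Their lack of a call is therefore little evidence against such responses. The T cell list was called as lower without the dimmest genes (adjusted p = 0.016). Cd8a, a marker of cytotoxic T cells, changed by -0.50 ± 0.16, the chemokine Ccl5 by -0.38 ± 0.10 and the macrophage lysozyme Lyz2 by 0.48 ± 0.17 (0.31 without infected 3, and 0.18 as the mean of its probe sets). Laptm5 changed by 0.53 ± 0.13 and passed without infected 1 (adjusted p = 0.0458) and as the mean of its probe sets (0.0383). Among interferon targets, Igtp changed by -0.37 ± 0.17 (-0.24 without uninfected 3) and Isg15 by 0.33 ± 0.15 (0.19 without uninfected 2, and 0.12 without uninfected 1 and 2). Nothing passed or was called in the lists of tight junctions (0.835), ion transport (0.415), cholesterol synthesis (0.508) and smooth muscle (0.773). The same held for enteric neurons and glia (0.185), endothelial cells (0.923), stomach and Brunner glands (0.576), adipose tissue (0.962), red blood cells (0.508), circadian clock (0.773) and immediate early and heat shock genes (0.723). Among these 11 lists 1 gene was called when adjusted over the list alone, the neuronal Syt1, which was lower. The neuronal list was called as lower without infected 3 (adjusted p = 0.0455). In the fibroblast list (camera adjusted p = 0.359) Pdgfra fell (-0.52 ± 0.10; limma adjusted p = 0.039). The other 23 of 24 did not pass, and 2 were lower when adjusted over the list alone. A second probe set of Pdgfra went the other way (0.74 ± 0.32). The call of Pdgfra was lost in 7 of 8 fits without 1 mouse (adjusted p up to 0.127 without infected 4). The chloride channel Cftr changed by -0.14 ± 0.18, Cldn4 by 0.46 ± 0.20 (0.25 without uninfected 2, and 0.24 without uninfected 1 and 2) and the calcium-binding S100g by -0.95 ± 0.28. That of S100g was -0.61 without uninfected 1 and 2 and -0.64 as the mean of its probe sets. Median and camera direction differed in sign for eosinophils (-0.04, up), endothelial cells (-0.04, up) and adipose tissue (0.01, down). Median and mean differed in sign for eosinophils, endothelial cells and MHC class II (-0.05 and 0.06).

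Transcripts of the exocrine pancreas differed between mice of the uninfected group. The signal of the trypsinogen gene Prss2 was 3389, 3832, 427 and 70.4 in uninfected 1 to 4 and 4.1, 276.4, 17.6 and 10.7 in infected 1 to 4. Its log2 change of -4.13 ± 1.16 did not pass (limma adjusted p = 0.188; 0.0468 without uninfected 4). Of 16 genes of this list none passed; 1 was higher and 8 were lower when adjusted over the list alone. Ctrb1, a chymotrypsinogen, changed by -2.39 ± 0.72 (limma adjusted p = 0.0381 without uninfected 4), Reg1 by -1.06 ± 0.29 (-0.69 without infected 3, adjusted p = 0.0317) and Pnliprp2 by 0.62 ± 0.17. The list fell by camera (adjusted p = 0.000807; adjusted p = 0.448 with an estimated correlation) and was not called without uninfected 1 and 2 (adjusted p = 0.823), where the change of Prss2 was -2.03 and that of Ctrb1 -0.81. None of 8 genes of the distal small intestine passed and 2 were lower when adjusted over the list alone, Muc3 and Cubn (-0.89 ± 0.29; 0.0354 without infected 3; -0.52 as the mean of its probe sets). The distal list fell by camera (adjusted p = 0.0285; adjusted p = 0.281 with an estimated correlation). Its call was lost without uninfected 2 (0.0545), uninfected 4 (0.0542), infected 1 (0.124), infected 2 (0.0691) or infected 4 (0.0507), by camera on ranks (0.176) and without an intensity trend (0.0515). Without uninfected 1 and 2, limma called 17 higher genes and 1 lower gene, and 16 of the 60 genes remained called. Beside Fcer1a and the xenobiotic genes, Arfgap2, Atp1b2, Ccl9, Clca1, Dipk2a, Gstm2, Il18, Itln1, Mmp7, Nhlh1, Pdgfra, Pmel, Pou2af1, Slc46a1, Slc6a20b, Spink4 and Znrf2 lost their call, with adjusted p from 0.0531 for Spink4 to 0.337 for Gstm2 and Pdgfra. Without another pair of uninfected mice, between 12 and 36 genes were called.

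**Figure D5:**
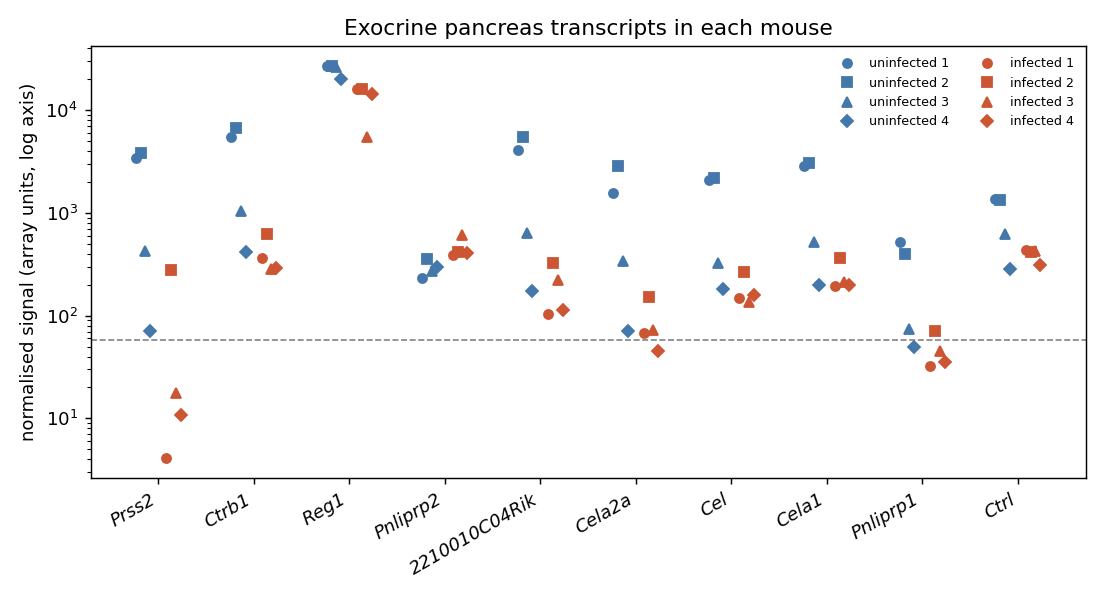
Normalised array signal (log axis) of 10 genes of the exocrine pancreas list in each mouse; colour gives the group, the marker shape the mouse number, and the dashed line the highest yeast control signal, 58.1. Uninfected 1 and 2 lie above the other 6 mice for most of the genes, as for Prss2 at 3389 and 3832.

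Further genes with the largest changes were outside the lists. Mbl2, a mannose-binding lectin of the complement system, rose from 126 ± 33.3 to 950.4 ± 212.9 (2.77 ± 0.20; limma adjusted p = 3.39e-05). The pentraxin gene Mptx1 rose from 306 ± 61.5 to 1190 ± 184.8 (1.91 ± 0.16; adjusted p = 9.16e-05) and Tent5c from 138 ± 27.7 to 400.6 ± 54.7 (1.44 ± 0.17). Atp1b2 rose by its brighter probe set (1.39 ± 0.22), with a mean below the yeast control in both groups, and a second probe set went the other way (-0.78 ± 0.35). Pmel (-1.57 ± 0.25), Nhlh1 (-1.39 ± 0.27), Arfgap2 (-0.99 ± 0.19) and Dipk2a (-0.85 ± 0.17) fell. The infected means of Pmel and Nhlh1, at 27.9 and 14, lay below the yeast control. With 1 or 64 added before taking logs in place of 16, the change was 2.30 or 0.65 for Atp1b2 and -2.23 or -0.68 for Nhlh1, whose call was lost with 1 added (adjusted p = 0.0709). That of Pmel was -0.95 with 64 added. The calls of Nhlh1, Arfgap2 and Dipk2a were lost in 7, 5 and 7 of 8 fits without 1 mouse (adjusted p up to 0.133 without uninfected 3, 0.142 without uninfected 2 and 0.121 without infected 3). For 20 called genes the array held 31 other probe sets, of which 26 changed in the same direction and 5, of Aldh1a1, Atp1b2, Pdgfra and Znrf2, in the other. The other probe set of Aldh1a1, with a mean log2 signal of 5.47 against 14.05, changed by 0.34 ± 0.33. With the mean of all probe sets of a gene, the calls of Aldh1a1 (log2 change -0.31), Atp1b2 (0.31), Ces1d (-0.61), Clca1 (0.54) and Gstm2 (-0.54) were lost. So were those of Igh-VS107 (0.80), Pou2af1 (0.76), Znrf2 (0.23), Ly6d (0.60) and St6gal1 (0.92), and the change of Pdgfra turned to 0.10. Hsd17b4, Dipk2a and Itln1 also lost their call, but each has 1 probe set, so their own values did not change. Their loss came from the fit and adjustment over all genes. The median SE of all log2 changes was 0.20, and the number of arrays limits this precision.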

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

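The tests of the enterocyte share, of a more distal piece of gut and of pancreas tissue were chosen after the result was seen. So were those of an effect of infection on pancreas transcripts and of lymphoid follicles. The test of the splits of the mice was written before. Leaving out pairs of uninfected mice was chosen after the data were seen. The test of the pancreas-rich arrays as a cause of the xenobiotic change rests on such a fit, and so was not planned beforehand. The rule for the distal test was tightened, by adding a bootstrap interval, after its first value was seen.

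The 8 mice can be split into 4 and 4 in 35 ways. The real split gave 60 changed genes by limma and the highest of the other splits 0. Thus 1 of 35 splits gave as many, the lowest share that 8 mice can give, which does not exclude chance. For gene lists the real split gave 14 and the highest other split 11, and 1 of 35 gave as many. The split with 11 lists kept 3 mice of each group together. Among the 18 splits with 2 mice of each group on either side, camera called at most 6 lists and limma 0 genes. In most of these 18 splits camera called at least 1 list, although infection was balanced between the sides. Camera with the preset correlation can thus call lists where infection does not differ, and its list calls are weaker evidence than their adjusted p.

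Transcripts of the exocrine pancreas were highest in uninfected 1 and 2. They were the top pair of the 8 for 11 of 16 pancreas genes, and without them the list's median log2 change moved from -1.05 to -0.228. Because these mice were picked for their pancreas signal, neither value could have come out the other way, and neither decides between explanations. The mean log2 signal of the list in uninfected 3 (8.66) also lay above that of each infected mouse (7.78, 8.54, 7.85 and 7.77), while that in uninfected 4 (7.73) lay below them. Pancreas tissue in some dissected pieces and lower expression with infection both stay open.

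The lower xenobiotic metabolism genes were set against 3 technical explanations. A smaller share of enterocyte RNA as the whole cause would lower enterocyte genes alike. In these mice the list's median lay lower than that of 45 other enterocyte genes (difference -0.41), of which 1 fell and 0 rose. The 95% bootstrap interval of the difference (-0.67 to -0.16, 10000 draws) resamples genes and not mice. It does not measure the spread between mice and leaves this explanation open. The median log2 change of the other genes was -0.106, so a smaller share may also be part of the change. Uninfected 1 and 2 alone were argued against as the whole cause, as the median log2 change without them was -0.456 against -0.515 with them. None of the 8 called genes passed in that fit to 6 mice. The fit kept uninfected 3, whose pancreas list mean (8.66) lay above each infected mouse, so pancreas tissue as such stays open. Uninfected 4, lowest in pancreas signal (7.73), had the lowest xenobiotic list mean of the uninfected mice (10.77). That mean still lay above each infected mouse (10.43, 10.57, 10.10 and 10.33). A more distal piece of gut in infected mice cannot be told apart. The 5 distal genes above the yeast controls had a median log2 change of -0.679, opposite to what such a piece predicts for them. The 95% bootstrap interval (-1.05 to 0.02) reached past 0, and it too resamples genes and not mice. A set of genes that mark proximal enterocytes was not tested. An effect of infection may account for the change, and stays a hypothesis.

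The B cell genes were higher in infected 3 and 4 than in infected 1 and 2. Within groups the 15 genes varied together with a mean correlation of 0.375, against 0.076 for the 95th percentile of 1000 random lists of that size matched on expression. Such a correlation was not particular to B cell genes. It was 0.582 for the exocrine pancreas and 0.487 for the smooth muscle list, while many other lists lay below 0.076. Uneven sampling of lymphoid follicles between pieces is a candidate explanation, but B cell numbers that differ between mice would give the same correlation. An increase of B cells with infection stays open, since the groups overlapped and the list was not called with an estimated correlation (adjusted p = 0.407).

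Of 392 groups of 4 mice tested for 1 mouse far from the others, 22 had such a mouse, where chance gives about 1 in 20 groups, or 19.6. Among uninfected mice, the signal of Adh1 was 10100 in uninfected 2 (others 8850 to 9000) and of Alox15 14.8 in uninfected 3 (66.6 to 78.3). That of Cck was 2060 in uninfected 4 (2650 to 2720). Apoa4 was at 71000 in uninfected 4 and at 74500 in each of the others. Quantile normalisation gives equal ranks the same value, so these equal signals are a tie in rank, and the flag of Apoa4 rests on it. The signal of Cldn4 was 1310 in uninfected 2 (2290 to 2520), of Cubn 4350 in uninfected 4 (3320 to 3410), of Gstm2 2040 in uninfected 4 (3040 to 3130) and of Ifng 48.2 in uninfected 1 (5.8 to 8.24). That of Igha was 34300 in uninfected 3 (45200 to 46700), of Igkv10-96 3050 in uninfected 1 (1770 to 1920), of Mfsd4a 253 in uninfected 1 (170 to 179) and of Reg1 20200 in uninfected 4 (26100 to 27100). Among infected mice, Fbln1 was at 3010 in infected 1 (2800 to 2810), Mcm3 at 263 in infected 1 (313 to 322), Mpo at 28 in infected 4 (8.33 to 9.99), Reg1 at 5440 in infected 3 (14300 to 16100) and Sct at 3210 in infected 3 (2750 to 2770).

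The mean log2 signal of the inflammatory cytokine list was 6.49 in infected 1 (others 6.74 to 6.76) and that of the interferon-gamma list 7.72 in infected 1 (7.88 to 7.9). That of the fatty acid oxidation list was 10.19 in uninfected 1 (10.04 to 10.06) and 9.78 in infected 3 (9.98 to 10.01), and that of the exocrine pancreas list 8.54 in infected 2 (7.77 to 7.85).

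Outside the gene table, 1589 probe sets carried no gene or several genes in the annotation. Tested by limma, 17 of them were higher and 1 was lower in infected mice. Of these, 7 were annotated to several genes. The largest changes among the 7 were 3.88 ± 0.22 (1551 ± 541.5 against 87.05 ± 16.24), 2.62 ± 0.39 (311 ± 99.44 against 41.26 ± 30.19, the latter below the yeast control) and 2.07 ± 0.19 (22200 ± 3686 against 5380 ± 1344), with limma adjusted p of 6.09e-06, 0.00951 and 0.000337.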

How the results depend on the processing

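Leaving out pairs of uninfected mice was chosen after the data were seen; all other alternatives were planned. Of 1256 gene values without 1 mouse, for 157 genes, 1078 kept direction and side of the threshold, 163 lost a call, 7 gained one and 8 turned; of 1539 under other alternatives, 1394 kept both, 131 lost a call, 9 gained one and 5 turned. For lists these were 269, 10, 9 and 24 of 312 without 1 mouse and 414, 29, 6 and 13 of 462 otherwise. Without 1 mouse, 35 to 51 genes were called (21 to 28 higher, 13 to 25 lower) and 12 to 17 lists (5 to 7 higher, 7 to 10 lower), with fewer mice in the fit. Without an intensity trend 27 genes were called (4 lower), over every probe set 56 were higher, and at an adjusted p of 0.10 the count was 106 (53 higher, 53 lower). With an estimated correlation 1 list was called (1 higher, 0 lower) and by fry 7 (3 higher, 4 lower).

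Leaving out 2 uninfected mice left 18 genes without 1 and 2 (17 higher, 1 lower), 17 without 1 and 3 (14, 3), 22 without 1 and 4 (19, 3), 12 without 2 and 3 (10, 2), 17 without 2 and 4 (12, 5) and 36 without 3 and 4 (15, 21). Correlations within groups averaged 0.8149 over the most variable 33.3% of probe sets. The mouse number as a block (replicate block) gave 54 genes (26 higher, 28 lower), 45 of them shared with the 60, and 14 lists; equally numbered mice correlated at -0.016, 0.008, 0.029 and 0.018 in their deviations, and 1 of 4 had its own number as best partner, so the numbers were not taken as pairs. Prss2 passed with the block (adjusted p = 0.0482). No list called without a block was lost with it, while the list of adipose tissue turned (adjusted p = 0.888).

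Without the dimmest genes, the direction turned for inflammatory cytokines (adjusted p = 0.215), type I interferon, tight junctions, smooth muscle and endothelial cells (0.907 each), enteric neurons (0.988) and adipose tissue (0.958), and the distal intestine list had too few genes. With the mean of probe sets it turned for Il4 (log2 change -0.022), Pdgfra (0.097), type I interferon (adjusted p = 0.987) and endothelial cells (0.786), and with 1 added before the log for adipose tissue (0.974). Without uninfected 1 and 2 it turned for Il4 (-0.102), Il6 (-0.216), Tff2 (0.011), tight junctions (adjusted p = 0.785) and immediate early genes (0.561). Without 1 mouse it turned at least once for Cftr (log2 change -0.281 to 0.014), Il17a (-0.366 to 0.054), Il4 (-0.066 to 0.339) and Il6 (-0.143 to 0.221). It also turned for the lists (adjusted p) of macrophages (0.11 to 0.917), eosinophils (0.49 to 0.968), neutrophils (0.573 to 0.942), type I interferon (0.672 to 0.987), MHC class II (0.257 to 0.9), tight junctions (0.477 to 0.987), smooth muscle (0.082 to 0.936), endothelial cells (0.636 to 0.987), stomach and Brunner glands (0.346 to 0.927), adipose tissue (0.59 to 0.956) and immediate early genes (0.2 to 0.936). None of these lists was called with all 8 mice, and the cause was not tested. Signals under the yeast control of 58.1 limit what can be said of the cytokine genes.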

Other observations

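The lists of retinoid and of peroxisomal genes were written after the main result was seen. The prediction for retinoid genes was written before its test was run, and that for peroxisomal genes after part of the result was seen. The following genes outside the lists were chosen after their values were seen. Gpx2, a glutathione peroxidase of the intestinal epithelium, rose from 4491 ± 675 to 8105 ± 1348 (log2 change 0.84 ± 0.14; limma adjusted p = 0.0141, and 0.0552 without uninfected 2). Cyba, a subunit of NADPH oxidases, rose from 960.7 ± 158.8 to 1692 ± 162.5 (0.81 ± 0.12) and the inflammatory caspase Casp4 from 249 ± 38.9 to 500.3 ± 60.9 (0.97 ± 0.14). In contrast Casp1, the caspase that activates Il18, fell from 2489 ± 65.2 to 1759 ± 215.5 (-0.51 ± 0.09), as Il18 did; its call was lost in 6 of 8 fits without 1 mouse (adjusted p up to 0.0997 without uninfected 2). The sialyltransferase gene St6gal1 rose from 124.5 ± 13 to 293.9 ± 32.7 (1.14 ± 0.16) and the surface protein gene Ly6d from 192 ± 29.6 to 403.6 ± 55.4 (1.01 ± 0.15). With the mean of all probe sets both lost their call, with 0.92 for St6gal1 (adjusted p = 0.161) and 0.60 for Ly6d (adjusted p = 0.255). Without an intensity trend in the variance the calls of Gpx2 (adjusted p = 0.117), Cyba (0.0712) and Casp1 (0.172) were lost. Without uninfected 1 and 2 together, an alternative chosen after the data were seen, Gpx2, Casp4, Casp1, St6gal1 and Ly6d lost theirs (adjusted p = 0.0883, 0.115, 0.281, 0.0738 and 0.0778).

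The called proteases Cma2, Mcpt1 and Mcpt2 follow one another in the gene order of GRCm38.p6 on chromosome 14, with Cma1 on one side and Mcpt9, Mcpt4, Mcpt8 and Ctsg on the other. Mcpt9 had no probe set of its own here, and 1 annotated to both Cma2 and Mcpt9 changed by 3.88 ± 0.22 and does not separate them. Signal shared between the probe sets of the called proteases was not tested. The log2 change was 4.41 ± 0.19 for Cma2, 6.18 ± 0.25 for Mcpt1 and 6.65 ± 0.33 for Mcpt2. It was 0.08 ± 0.26 for Cma1, 0.82 ± 0.34 for Mcpt4, 1.09 ± 0.39 for Mcpt8, 0.22 ± 0.29 for Ctsg and -0.14 ± 0.14 for Gzmb at the far end, none of which passed. The mean signals of Mcpt4, Mcpt8 and Ctsg lay below the yeast control in both groups, which limits what their changes can show.

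Retsat, which saturates retinol, fell (-0.71 ± 0.10; limma adjusted p = 0.00894), as did Aldh1a1 and Adh1, so it was asked whether vitamin A handling fell as a group. Among 19 other retinoid genes none passed, 14 had a negative change and the median was -0.18; camera gave p = 0.018 with its preset correlation and p = 0.109 with an estimated correlation, which leaves the hypothesis open. Idh1 (-0.52 ± 0.08) and Hsd17b4 (-0.46 ± 0.09), enzymes found in peroxisomes, fell as well, the latter with a call lost in 7 of 8 fits without 1 mouse (adjusted p up to 0.157 without uninfected 1). Without an intensity trend the calls of Retsat (adjusted p = 0.0894), Idh1 (0.143) and Hsd17b4 (0.235) were lost, and without uninfected 1 and 2 together they were lost as well (0.114, 0.0531 and 0.3). That of Hsd17b4 was also lost in the as-deposited values (0.0529) and with 64 added before the log (0.0535). It was lost as well with the mean of probe sets (0.0575), although this gene has a single probe set. Among 31 other peroxisomal genes none passed, 22 had a negative change and the median was -0.14; camera gave p = 0.000166 with its preset correlation and p = 0.0517 with an estimated correlation, so that a fall of peroxisomal enzymes as a group may or may not hold.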
